A study of Mus musculus with 8 samples.

How the data were processed

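The 8 mouse libraries were analysed, 4 from control and 4 from LKB1-deficient CD8+ T cells activated for 48 hours; the labels' titles give the groups and the replicate numbers. Per the labels' protocols, RNA was reverse transcribed with barcoded oligo-dT primers, the samples were pooled before PCR enrichment according to qPCR values, and the libraries keep the strand and count 3' ends. No molecular identifiers are stated, so PCR copies may be counted more than once. The authors deposited raw read counts per gene symbol, 1 table per library. Per the submitters' processing notes the reads were aligned with STAR to mm10, and the counting program, versions, annotation and treatment of reads shared between copies are not given in the sources used here. The 5 closing lines that name no gene were kept out of library sizes and tests. Counts outside annotated genes came to 12.1% to 17.5% of the sum of gene, ambiguous and unannotated counts. Alignments to several places came to 2.92 to 3.502 per gene count in the control and 2.213 to 2.648 in the LKB1-deficient libraries. The deposited tables hold 24421 genes.

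Gene counts came to 7090252 to 12211930 per control library and 3454388 to 6356125 per LKB1-deficient library, and 12499 to 13667 genes had at least 1 count. The lower depth makes low genes less precise in the LKB1-deficient libraries. Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 11.6 to 49.05), so none was counted as a duplicate.

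Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and the groups were compared with the robust quasi-likelihood test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes. Gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members, adjusted over the tested lists; camera with an estimated correlation and fry were run beside it. Of 32 lists fixed, 29 were tested, the lists of gamma-delta T and NK cell and of B cell markers had too few tested members, and the list of mitochondrial genome genes was not analysed here. The members Vsir, Trac, Trbc1, Trbc2, Trdc, Tcrg-C1, Tcrg-C2, Scart1, Ighm, Ighd, Igkc and Ahsp were likewise not analysed here.

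The genes named in the text were chosen by a rule set before the data were examined: Stk11; the 15 genes with the largest rise and the 15 with the largest fall among called genes with non-overlapping libraries and a mean CPM of at least 10; the 5 genes with the smallest p in each direction; up to 2 members of each list that rose and 2 that fell; and Il6, Il11, Cxcl2, Ifng, Tnf, Il2, Il17a, Stat3 and Socs3. Predicted genes and clone names were skipped, and some genes that the rule takes are not reported here. Coordinates and transcript lengths come from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, and 99.6% of tested genes had a length. The length of a gene is that of its longest annotated transcript.

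Alternatives were DESeq2 1.42.0 size factors and its Wald test, upper quartile and total count scaling, no filter, a mean CPM of at least 10, limma-voom, a replicate block, a term for the first letters of the sample identifiers, each library left out, a stricter adjusted p of 0.01 and a test against a 1.5-fold change. Chosen after the data were seen were thinning every library to 3454388 counts, removing each library's trend on transcript length (lowess span 0.3), with or without GC content, leaving out both LKB1-deficient replicates 2 and 4, using only replicates 1 to 3 or only the libraries whose identifiers start with EU, and a term for high Xist; the gene lists were also run with upper quartile and total count scaling, no filter and the prefix term. The test was checked on simulated counts for 10396 genes, made from the real means, library sizes and dispersions with 200 genes changed: for LKB1-deficient against control the quasi-likelihood test recovered 4.48% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 93.9% of those changed 4-fold, with 5 false calls among 109. The same simulation gave DESeq2 29 false calls among 150. Intervals of list medians come from 2000 bootstrap draws over list members, which cover the spread between members and not between libraries.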

Results

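Gene expression was measured by 3' RNA-seq in mouse CD8+ T cells, the T cells that kill infected and tumour cells, after naive cells had been activated for 48 hours with plate-bound antibodies against CD3 and CD28. The labels give 4 control libraries from LKB1 wild-type cells and 4 libraries from LKB1-deficient cells. LKB1, encoded by Stk11, is a kinase that activates AMPK and related kinases. The control libraries held 10751427, 11950018, 12211930 and 7090252 gene counts for replicates 1 to 4, and the LKB1-deficient libraries held 3454388, 3864046, 6356125 and 4303901. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples. Values below are CPM, counts scaled to library size with TMM factors, given as mean ± SD with n = 4 per group. Fold changes are LKB1-deficient against control with Benjamini-Hochberg adjusted p-values. Their standard errors (SE) are approximate, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic.

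The targeted gene came first. Stk11 lies on chromosome 10 from 80115803 to 80130682 on the plus strand of GRCm38, where the annotation lists it as a protein-coding gene (ENSMUSG00000003068.16). Its CPM was 101, 67.8, 82 and 77 in control replicates 1 to 4, and 76.5, 70.8, 107 and 64.4 in LKB1-deficient replicates 1 to 4. The log2 fold change was -0.03 ± 0.19 (SE, adjusted p = 0.911), and the sign of this small value differed between processing alternatives. The libraries count 3' tags and the labels do not state which part of the gene was deleted, so these values do not check the genotype labels.

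The question set by the design was which transcripts differ between activated CD8+ T cells with and without LKB1. Of 27 tested cytokine and chemokine genes, 17 rose in the LKB1-deficient cells, among them Il9, Csf2, Il3, Il13 and Ifng (3.16-fold), and 3 fell. Of 31 tested interferon-response genes, 14 fell, among them Irf7, Mx1 and Gbp2, and none rose. Both lists passed with a preset correlation between genes but not with an estimated one (adjusted p = 0.455 for each). The receptor genes Cd8a, Klrk1 and Klrd1 were lower. Of 10396 genes tested, 2337 passed an adjusted p of 0.05, 1286 higher and 1051 lower, and 508 of the higher and 302 of the lower genes differed at least 2-fold. The groups did not overlap in 26.1% of the tested genes, against 2.86% by chance. The first principal component held 56.4% of the variance and separated the groups. LKB1-deficient replicates 2 and 4 lay at 51.7 and 54.4 on it, LKB1-deficient replicates 1 and 3 at 12.5 and 6.79, and the controls between -37.9 and -21.7. The count depended on single libraries, falling to 1011 without control replicate 3, 1303 without control replicate 4, 1113 without LKB1-deficient replicate 2 and 1017 without LKB1-deficient replicate 4. Without both LKB1-deficient replicates 2 and 4, 260 genes passed, and 54 of the 121 called genes that the naming rule takes kept their calls. These libraries lay farthest from the controls, and leaving them out makes the group smaller. A fall in calls thus does not show that the differences rest on them. The sample identifiers start with ET for replicate 1 and EU for replicates 2 to 4 of both groups; EU libraries alone gave 1172 higher and 666 lower genes, and the ET libraries, 1 per group, allow no test. Scaling by total count moved the median log2 fold change of all genes from 0.00 to -0.16 and split the calls into 829 higher and 1576 lower, and upper quartile scaling gave 1023 higher and 1446 lower.

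**Figure D1:**
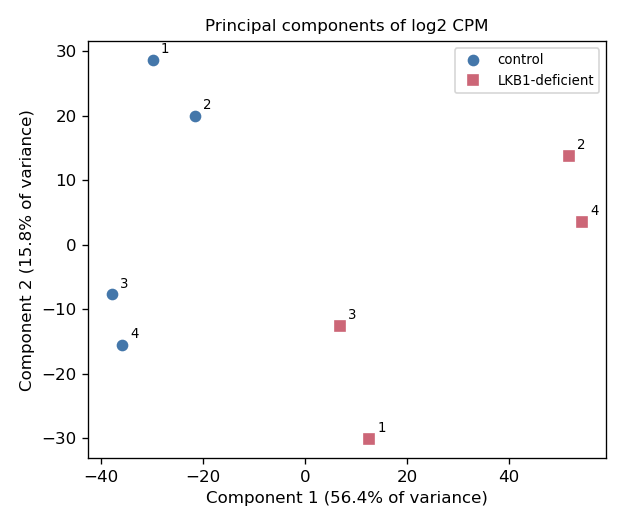
Principal components of log2 CPM of the tested genes, with component 1 on the x axis and component 2 on the y axis, for 4 control libraries (circles) and 4 LKB1-deficient libraries (squares), each marked with its replicate number. The controls lie between -37.9 and -21.7 on component 1 and the LKB1-deficient libraries between 6.79 and 54.4.

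The genes with the largest rise included cytokine genes and a cytokine receptor gene. Il9, a type 2 cytokine gene on chromosome 13 (56479277 to 56482246, minus strand), went from 1.57 ± 0.97 to 166 ± 123 CPM (log2 fold change 6.77 ± 0.92, adjusted p = 0.00341), with 12 CPM in LKB1-deficient replicate 3 and 124 to 281 in the other LKB1-deficient libraries. Il24, a cytokine of the IL-10 family, went from 7.1 ± 7.81 to 143 ± 43.8 CPM, and Csf2, encoding GM-CSF, from 3.95 ± 1.45 to 57.1 ± 43.9 CPM. Il3, a growth factor of myeloid cells and mast cells, rose 11.9-fold and the type 2 cytokine Il13 rose 9.83-fold. Inhba, encoding an activin subunit, rose 13.5-fold, and Csf2rb, the shared beta chain of the receptors for IL-3, IL-5 and GM-CSF, rose 12.3-fold. Atp2b4, a plasma membrane calcium pump, had the smallest p of all genes and went from 5.32 ± 1.32 to 50.2 ± 3.31 CPM (adjusted p = 6.04e-05). The other genes with the largest rise were Car2 (9.84-fold), Lmo2 (8.67-fold), Timp3 (8.54-fold), Rai14 (7.94-fold), Itpripl2 (7.73-fold), Epn2 (7.16-fold) and Lrrk1 (5.96-fold). Runx2, Chsy1 and Furin, of which Runx2 encodes a Runt-family transcription factor and Furin a proprotein convertase, had small p-values and rose 3.96-, 2.28- and 3.39-fold. Without both LKB1-deficient replicates 2 and 4 the calls of Csf2rb, Il13, Lmo2, Timp3 and Rai14 ended, and the adjusted p of Il13 was then 0.0614 at a log2 fold change of 2.85, while Il9, Il24, Csf2, Il3 and Atp2b4 kept theirs. Of 5 tested markers of mast cells and basophils, a list chosen after values were seen, 2 rose: Gata2 went from 1.23 ± 0.365 to 5.22 ± 4.44 CPM (adjusted p = 0.0422) and Il1rl1 from 3.44 ± 1.43 to 9.09 ± 3.78 CPM (adjusted p = 0.0296). In LKB1-deficient replicates 2 and 4 Gata2 was at 9.62 and 8.36 CPM, Il9 at 246 and 281 CPM and Csf2rb at 31.5 and 31.3 CPM, each above its values in LKB1-deficient replicates 1 (0.563, 124 and 3.94 CPM) and 3 (2.36, 12 and 8.66 CPM). Csf2, Il13, Inhba and Il3 followed this order too. They were at 28.1, 46.4, 35.2 and 107 CPM in LKB1-deficient replicate 1 and 66.7, 53.6, 38.8 and 111 CPM in replicate 2. For Inhba and Il3 these values were close. Runx2 (53.2, 66.7, 43.9 and 64.4 CPM in LKB1-deficient replicates 1 to 4) and Lrrk1 (23.4, 50.7, 21.1 and 50.7 CPM) had the same order. LKB1-deficient replicates 2 and 4 also lay farthest out on the first component, so the order is not particular to cytokine or mast cell genes. Ifng and Il24, which also rose, did not follow it, with 3100 and 1980 CPM and 153 and 124 CPM in LKB1-deficient replicates 1 and 2. Nor did Il2, at 14.1 and 12.4 CPM in LKB1-deficient replicates 1 and 4.

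Among the genes with the largest fall, Nrn1, encoding neuritin, went from 364 ± 125 to 30.7 ± 19.7 CPM (log2 fold change -3.54 ± 0.47, adjusted p = 0.00341). Id3, an inhibitor of E protein transcription factors, went from 44.3 ± 21.6 to 6.68 ± 2.02 CPM, and Ephx1, epoxide hydrolase, was 8.15-fold lower. Nrgn, Itm2a, Mgst2, Phf11b, Lrig1, Arl5c and Pyhin1 were 5.69-, 4.36-, 4.3-, 4.19-, 4.11-, 3.77- and 3.82-fold lower. Ifi27l2a, an interferon-inducible gene, went from 327 ± 45.2 to 59.7 ± 52.8 CPM. Among the genes with the smallest p, Irf7 was 2.91-fold, Il15ra (a subunit of the IL-15 receptor) 2.29-fold, Pla2g16 2.9-fold, Ldhb 5.01-fold and Bmyc 2.63-fold lower. Pou2af1 (4.4-fold lower) and Cxxc5 (3.92-fold lower) lost their calls without LKB1-deficient replicate 2 or replicate 4, where the adjusted p was at most 0.0688 and 0.0643. The calls of Pyhin1 and Arl5c ended without both of these libraries (adjusted p = 0.105 and 0.0556).

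**Figure D2:**
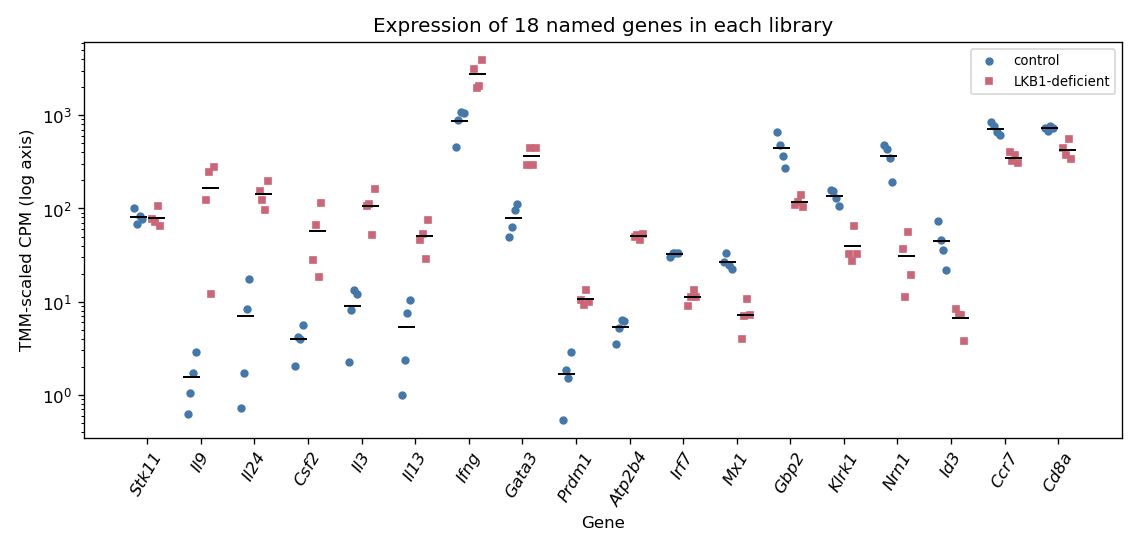
TMM-scaled CPM on a log axis (y) of 18 named genes (x) in each of 4 control libraries (circles) and 4 LKB1-deficient libraries (squares), with a black bar at each group mean. Il9 lies between 0.629 and 2.86 CPM in the controls and between 12 and 281 CPM in the LKB1-deficient libraries, while Stk11 overlaps between the groups.

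Among 36 inflammatory cytokine and chemokine genes fixed before the data were examined, 27 were tested, 17 rose, 3 fell and 7 did not pass (19 rose and 3 fell when adjusted over the list alone). The list passed (median log2 fold change 1.16, camera adjusted p = 0.00016 with a preset correlation, adjusted p = 0.455 with an estimated correlation). The 17 became 11 without control replicate 3, 10 without LKB1-deficient replicate 4 and 6 without both LKB1-deficient replicates 2 and 4. Il9 and Il3 had the smallest p of those that rose, and the fallers included Xcl1 (2130 ± 360 to 1010 ± 177 CPM) and Ltb (150 ± 42.8 to 48.3 ± 20.5 CPM), encoding lymphotactin and lymphotoxin beta. Xcl1 lost its call when the transcript length trend was removed (log2 fold change -0.61, adjusted p = 0.0883). Ifng went from 871 ± 295 to 2750 ± 900 CPM (log2 fold change 1.66 ± 0.31), and its adjusted p of 0.0088 became 0.051 without both LKB1-deficient replicates 2 and 4. Il2 rose 2.64-fold (adjusted p = 0.0405), a call that ended when any single library other than LKB1-deficient replicate 3 was left out (adjusted p at most 0.124). Tnf was 24.8 ± 4.95 in control and 28.2 ± 5.75 CPM in LKB1-deficient cells (adjusted p = 0.521). Il17a was 2.08 ± 0.76 and 1.4 ± 1.06 CPM (adjusted p = 0.56). Il6 (0.961 ± 0.584 and 1.99 ± 0.797 CPM), Il11 (0.757 ± 0.394 and 0.756 ± 0.118 CPM) and Cxcl2 (0.564 ± 0.203 and 1.59 ± 1.02 CPM) were under the count filter and were not tested.

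Of 20 genes listed as targets of STAT3, the transcription factor that IL-6 family cytokines activate, 16 were tested, 5 rose, 1 fell and 10 did not pass (6 rose and 1 fell when adjusted over the list alone). The list just passed (median 0.28, camera adjusted p = 0.0498, adjusted p = 0.455 with an estimated correlation), and this call ended under 14 other alternatives, including without control replicate 1 or 2 or LKB1-deficient replicate 1 or 3 (adjusted p between 0.0561 and 0.122). Pim1, a kinase, and Socs3, the feedback inhibitor of cytokine receptors, rose 2.81-fold and 2.75-fold. Bcl6 was 2.95-fold lower. Stat3 itself was 546 ± 25.4 and 573 ± 152 CPM (adjusted p = 0.813), and its sign flipped with upper quartile and total count scaling. In the list of CREB and CRTC targets, genes of cyclic AMP signalling, 4 of 21 rose and 3 fell, adjusted over the list alone as well, and the list did not pass (median 0.11, camera adjusted p = 0.561); its median turned to -0.07 with total count scaling. In this list 1 rose and 2 fell without LKB1-deficient replicate 4, 2 and 2 without control replicate 1, 2 or 3. The median was 0.05 without LKB1-deficient replicate 2, 0.06 without control replicate 1, 0.17 without LKB1-deficient replicate 1, 0.22 without control replicate 2 and 0.23 without LKB1-deficient replicate 3. Its named members were Id2 (1.99-fold higher), Pde4b (1.6-fold higher), Pde4d (1.73-fold lower) and Nr4a1 (2.13-fold lower). The call of Bcl6 ended without LKB1-deficient replicate 2 (adjusted p = 0.0536), that of Id2 without control replicate 3 (adjusted p = 0.0534), and that of Pde4b without control replicate 3 or LKB1-deficient replicate 4 (adjusted p at most 0.0666).

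Of 22 tested cytotoxic effector genes, 8 rose, 2 fell and 12 did not pass (9 rose and 2 fell when adjusted over the list alone; median 0.60, camera adjusted p = 0.014, adjusted p = 0.455 with an estimated correlation); among genes with a mean CPM of at least 10 the list did not pass (adjusted p = 0.0539). Prdm1, encoding the effector regulator Blimp-1, went from 1.69 ± 0.958 to 10.8 ± 1.79 CPM, and Zeb2, another effector regulator, from 18.8 ± 5.17 to 64 ± 21.5 CPM. The 2 that fell were the receptor genes Klrk1 (NKG2D, 137 ± 23.7 to 39.1 ± 16.8 CPM) and Klrd1 (CD94, 182 ± 41.9 to 50.4 ± 33.9 CPM). Of naive and memory T cell genes, 5 of 23 were higher and 3 lower (5 and 4 when adjusted over the list alone), and the list, with a median of 0.23 and a mean of -0.01, did not pass (camera adjusted p = 0.681); Satb1 and Lef1 rose 2.02-fold and 1.72-fold while Ccr7, the lymph node homing receptor, and Id3 fell. The median of this list was -0.01 with the length trend removed and 0.13, 0.15 and 0.11 without LKB1-deficient replicate 1, 2 or 3. Its counts were 3 higher and 5 lower with upper quartile scaling, 3 and 6 without LKB1-deficient replicate 3, and 3 and 3 without control replicate 2, 3 or 4 or LKB1-deficient replicate 2. Of 23 activation markers, 2 rose and none fell, also when adjusted over the list alone (median 0.25, camera adjusted p = 0.14). The median was 0.17 without control replicate 1. In this list 4 rose without control replicate 4 and 2 rose and 2 fell with upper quartile or total count scaling. The 2 that rose with all libraries and TMM scaling were Il2ra, the IL-2 receptor alpha chain (391 ± 100 to 1090 ± 114 CPM), and Irf4 (174 ± 10 to 270 ± 36.8 CPM). Of 13 inhibitory receptor and exhaustion genes, 2 rose and 3 fell, also when adjusted over the list alone (median -0.58, camera adjusted p = 0.182). Without LKB1-deficient replicate 3, 3 rose and 5 fell. The median was -0.37 without control replicate 2 and -0.36 without LKB1-deficient replicate 2. Havcr2, encoding TIM-3, rose 3.87-fold and Entpd1, encoding CD39, rose 4.77-fold, while Pdcd1, encoding PD-1, and Cd160 were 2.47-fold and 2.61-fold lower.

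Of 31 genes of the type I interferon response tested, 14 fell, none rose and 17 did not pass (17 fell when adjusted over the list alone; median -0.66, camera adjusted p = 1.2e-07, adjusted p = 0.455 with an estimated correlation). Irf7, a transcription factor that amplifies the interferon response, went from 32.5 ± 1.64 to 11.1 ± 1.72 CPM, Zbp1, a sensor of nucleic acids, from 72.4 ± 4.77 to 30.8 ± 5.79 CPM, Mx1, an antiviral GTPase, from 26.8 ± 4.64 to 7.23 ± 2.77 CPM, and Gbp2, a guanylate-binding protein, from 446 ± 169 to 117 ± 16.3 CPM. These 4 genes had lower values in all LKB1-deficient libraries than in any control library. The naming rule required this of Mx1 and Gbp2, and the groups did not overlap in 1968 of the 2337 called genes, so it is not particular to this list.

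Of 69 nuclear genes of the mitochondrial respiratory chain and ATP synthase, 26 fell and none rose (32 fell when adjusted over the list alone; median -0.42, camera adjusted p = 5.38e-10, adjusted p = 0.455 with an estimated correlation). Ndufc2, of complex I, went from 417 ± 39.7 to 250 ± 23.9 CPM and Cox6c, of complex IV, from 612 ± 76.9 to 353 ± 57.3 CPM. The 26 became 4 without control replicate 3, 7 without control replicate 4, 17 without control replicate 1, 5 without LKB1-deficient replicate 2 and 5 without LKB1-deficient replicate 4. Removing each library's trend on transcript length left 6 lower genes and a median of -0.12, and ended the call of Ndufc2 (log2 fold change -0.33, adjusted p = 0.113). Of 22 glycolysis genes, 1 rose and 2 fell, also when adjusted over the list alone (median -0.31, camera adjusted p = 0.0448, adjusted p = 0.678 with an estimated correlation). Hk2, hexokinase, went up from 221 ± 25 to 575 ± 87.7 CPM, and Ldhb, the lactate dehydrogenase B subunit, and Eno3 were 5.01-fold and 1.85-fold lower. The call of the glycolysis list ended without control replicate 3 or 4 or LKB1-deficient replicate 2 or 4 (adjusted p between 0.0793 and 0.212), and its adjusted p was 0.9 without both LKB1-deficient replicates 2 and 4. With upper quartile and total count scaling it was 0.0598 and 0.0794, and among genes with a mean CPM of at least 10 it was 0.0616. Without LKB1-deficient replicate 3, 5 glycolysis genes fell, and the median was -0.20 without LKB1-deficient replicate 2. In the fatty acid oxidation list 1 of 21 genes rose and 5 fell (1 and 6 when adjusted over the list alone; median -0.27, camera adjusted p = 0.0154, adjusted p = 0.455 with an estimated correlation). The call ended without LKB1-deficient replicate 1 (adjusted p = 0.0566), with the length trend removed (adjusted p = 0.0651) and in EU libraries alone (adjusted p = 0.0646). In this list 3 genes fell without control replicate 3. Decr1 and Acaa2, enzymes of beta oxidation, were 1.94-fold and 1.66-fold lower, and Ppargc1b, a coactivator of mitochondrial genes, was 2.05-fold higher. In the autophagy and lysosome list 1 of 35 rose and 8 fell (2 and 8 when adjusted over the list alone; median -0.23, camera adjusted p = 0.0254, adjusted p = 0.455 with an estimated correlation), with Ctsz 1.83-fold higher and Ctsl 2.43-fold lower. The call of Ctsl ended without LKB1-deficient replicate 4 (adjusted p = 0.061), and that of Ppargc1b without control replicate 2 or 3 or LKB1-deficient replicate 2 or 4 (adjusted p at most 0.0947). The autophagy and lysosome call ended without both LKB1-deficient replicates 2 and 4 (adjusted p = 0.144), with replicates 1 to 3 (adjusted p = 0.0507) and among genes with a mean CPM of at least 10 (adjusted p = 0.0616). Its 8 lower genes became 2 without control replicate 3 or LKB1-deficient replicate 2 or 4, and 3 without control replicate 1 or 4.

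The remaining metabolic lists did not pass. Of 25 TCA cycle genes 1 rose and 5 fell, also when adjusted over the list alone (median -0.18, camera adjusted p = 0.0985), including Ogdh (1.48-fold higher), Mdh1 (1.8-fold lower) and Sdhc (1.5-fold lower). In this list 0 rose and 1 fell without control replicate 3 or 4 or LKB1-deficient replicate 2 or 4, and the median was -0.28 without control replicate 1 or LKB1-deficient replicate 3. Of 21 hypoxia and HIF1 targets 2 fell, Ankrd37 and Plin2 (1 when adjusted over the list alone; median -0.29, camera adjusted p = 0.0985). This list passed without control replicate 1 or LKB1-deficient replicate 3 (adjusted p = 0.0338 and 0.00918, with 1 and 6 genes lower) and in EU libraries alone (adjusted p = 0.0395). Its median was -0.46 without LKB1-deficient replicate 3 and -0.15 without LKB1-deficient replicate 4. Of 28 serine, one-carbon and ATF4 genes 1 rose and 2 fell (0 and 1 when adjusted over the list alone; median -0.28, camera adjusted p = 0.15). These were Slc38a2, an amino acid transporter, and Psph and Ddit3. The list passed without control replicate 1 (adjusted p = 0.0239) and in EU libraries alone (adjusted p = 0.0197). In this list 5 genes fell without LKB1-deficient replicate 3, and the median was -0.18 without control replicate 4 and -0.425 without LKB1-deficient replicate 1. Of 22 cholesterol synthesis genes 2 rose and 2 fell (Pmvk and Nsdhl), also when adjusted over the list alone (median -0.20, camera adjusted p = 0.182). With total count scaling 0 rose and 4 fell, and 1 rose and 0 fell without control replicate 3 or LKB1-deficient replicate 2. Of 15 fatty acid synthesis genes 3 rose, also when adjusted over the list alone, Fasn and Elovl6 among them (median 0.12, camera adjusted p = 0.68). The median was -0.04 with total count scaling, -0.17 with the length trend removed and -0.00282 without LKB1-deficient replicate 4. It was 0.05 and 0.04 without control replicate 1 or 2, and 0.00368, 0.22 and 0.01 without LKB1-deficient replicate 1, 2 or 3. In this list 1 gene rose without control replicate 3 or 4 or LKB1-deficient replicate 2 or 4. Of 17 genes of the LKB1 complex, AMPK and related kinases only Sik3 passed, 1.42-fold higher (0 when adjusted over the list alone; median -0.06, camera adjusted p = 0.676). With total count scaling or without LKB1-deficient replicate 3, 2 genes of this list fell. Its median was -0.12 without control replicate 2, and -0.03, -0.15 and -0.04 without LKB1-deficient replicate 1, 3 or 4. Fasn and Sik3 lost their calls with the length trend removed (adjusted p = 0.313 and 0.426). The call of Plin2 ended when any single library other than LKB1-deficient replicate 3 was left out (adjusted p at most 0.102). Those of Slc38a2, Ddit3 and Ogdh ended without control replicate 2, 3 or 4 or LKB1-deficient replicate 2 or 4 (adjusted p at most 0.116, 0.108 and 0.091), and that of Slc38a2 also without LKB1-deficient replicate 1. Nsdhl lost its call when any library other than control replicate 2 or LKB1-deficient replicate 3 was left out (adjusted p at most 0.109). Elovl6 and Sdhc lost theirs without control replicate 3 or 4 or LKB1-deficient replicate 2 or 4 (adjusted p at most 0.0841 and 0.061), and Pmvk without control replicate 3 or LKB1-deficient replicate 2 or 4 (adjusted p at most 0.0669). Sik3 lost its call without control replicate 1 or 4 or LKB1-deficient replicate 2 (adjusted p at most 0.0579), and Psph without LKB1-deficient replicate 4 (adjusted p = 0.0534).

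Of 60 cytosolic ribosomal protein genes, 21 fell, 1 rose and 38 did not pass (23 and 1 when adjusted over the list alone; median -0.34, camera adjusted p = 2.39e-06, adjusted p = 0.455 with an estimated correlation). Rps4x went from 137 ± 15.9 to 87.8 ± 13.3 CPM, while Rpl24 was 1.65-fold higher. The 21 became 1 without control replicate 3, 3 without control replicate 4, 13 without control replicate 1, 6 without LKB1-deficient replicate 2 and 4 without LKB1-deficient replicate 4. With the length trend removed the list no longer passed (median -0.08, adjusted p = 0.242), nor did Rps4x (adjusted p = 0.0634). Of 29 ribosome biogenesis genes and MYC targets, 9 rose, none fell and 20 did not pass (15 and 1 when adjusted over the list alone; median 0.58, camera adjusted p = 0.000156, adjusted p = 0.455 with an estimated correlation). The 9 became 4 without control replicate 3 or LKB1-deficient replicate 2 or 4 and 5 without control replicate 4, and with total count scaling 5 rose and 1 fell. Nop2, an rRNA methyltransferase, and Cad, the enzyme that starts pyrimidine synthesis, rose 1.77-fold and 1.72-fold, and Cad lost its call with the length trend removed (adjusted p = 0.177). The call of Rpl24 ended without control replicate 1, 3 or 4 or LKB1-deficient replicate 2 or 4 (adjusted p at most 0.0969), and that of Rps4x without control replicate 3 (adjusted p = 0.0515). Ribosomal protein genes have many pseudogenes, and how reads shared between copies were counted is not given in the sources used here. Alignments to several places per gene count were lower in all LKB1-deficient libraries than in any control library.

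The cell cycle lists did not pass. Of 35 DNA replication genes 3 fell and none rose (1 when adjusted over the list alone; camera adjusted p = 0.68; median -0.06 and mean 0.02), with Rfc4 and Gins2 1.72-fold and 1.48-fold lower. Without control replicate 2, 4 rose and 3 fell, and 1 fell without control replicate 3 or 4 or LKB1-deficient replicate 2 or 4. Of 30 mitosis genes 1 rose and 2 fell, also when adjusted over the list alone (median 0.13, camera adjusted p = 0.561, and -0.03 with total count scaling), with Anln 2.21-fold higher and Cenpa and Ccnb2 1.8-fold and 1.49-fold lower. In the mitosis list 4 rose and 3 fell without LKB1-deficient replicate 1, and 3 and 2 without control replicate 2; the median was 0.08 without LKB1-deficient replicate 4. Of 22 p53 targets 8 rose and 3 fell (9 and 3 when adjusted over the list alone; median 0.37, camera adjusted p = 0.25; the median was -0.02 among genes with a mean CPM of at least 10). The 8 became 3 without control replicate 1, 3 or 4 or LKB1-deficient replicate 4, 4 without LKB1-deficient replicate 2 and 5 without control replicate 2. In this list 4 rose and 4 fell with upper quartile or total count scaling. Cdkn1a, the cell cycle inhibitor p21, went from 165 ± 76.5 to 496 ± 68.3 CPM and Zmat3 rose 2.56-fold, while Sesn1 and the death receptor Fas were 2.79-fold and 1.79-fold lower. Of 13 BCL2 family genes 2 rose and 2 fell, also when adjusted over the list alone (median -0.20, camera adjusted p = 0.182). Bcl2l1 and Bcl2, which protect cells from death, rose 1.69-fold and 1.42-fold, Bcl2l11, the death-promoting BIM, was 2.26-fold lower, and Bcl2a1b, one of several near-identical copies, was 1.93-fold lower. Bcl2 lost its call when any single library other than LKB1-deficient replicate 4 was left out (adjusted p at most 0.0801), with the length trend removed (adjusted p = 0.643) and with total count scaling (adjusted p = 0.165). Gins2, Anln and Ccnb2 lost theirs without control replicate 3 or 4 or LKB1-deficient replicate 2 or 4 (adjusted p at most 0.0683, 0.0621 and 0.0664).

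Markers of cell identity were examined for the T cells and for other cells that the culture could hold. Of 14 CD8+ T cell identity genes 1 rose and 4 fell (1 and 7 when adjusted over the list alone; median -0.37, camera adjusted p = 0.0766), with Cd8a from 721 ± 38.3 to 425 ± 96.3 CPM and Cd3d from 794 ± 53.5 to 367 ± 68.1 CPM lower, and Runx3, a transcription factor of CD8+ T cells, from 168 ± 22.2 to 395 ± 50.7 CPM higher. This list passed without LKB1-deficient replicate 3 (adjusted p = 0.036), while 2 genes fell without control replicate 1 or 3 or LKB1-deficient replicate 2 or 4. Cd4 was 0.554 CPM in control and 0.253 CPM in LKB1-deficient cells on average, with 22 and 4 counts in all. In the list of CD4 and regulatory T cell genes 3 of 7 rose and 1 fell (4 and 1 when adjusted over the list alone; median 0.66, camera adjusted p = 0.153). With no filter on low counts, which brought in 5 more members, the median was -0.17. It was 0.15, 0.39, 0.24 and 0.35 without LKB1-deficient replicate 1, 2, 3 or 4. Gata3, a transcription factor of T cell development and type 2 responses, went from 79.6 ± 28.2 to 368 ± 89.3 CPM. Izumo1r was 2.13-fold lower, a call that ended when any library other than LKB1-deficient replicate 1 or 3 was left out (adjusted p at most 0.101). Fewer than 5 markers of gamma-delta T and NK cells and of B cells passed the filter, so those lists were not tested; Klra7, of a family of similar genes that can share reads, was 3.15-fold lower, H2-Aa and H2-Ab1 were 3.22-fold and 2.91-fold higher, and Cd79b was 1.92-fold lower. H2-Ab1 lost its call without control replicate 3 or 4 or LKB1-deficient replicate 2, 3 or 4 (adjusted p at most 0.0743), and Klra7 without LKB1-deficient replicate 2 or 4 (adjusted p at most 0.0547). Of 5 macrophage and granulocyte markers, 1 rose (Ccr2) and 1 fell (Ctss, which lost its call without LKB1-deficient replicate 4, adjusted p = 0.0599), also when adjusted over the list alone (median 0.13, camera adjusted p = 0.745). The median was -0.03 with total count scaling, -0.06 with no filter and -0.12 without LKB1-deficient replicate 1, and it was 0.04, 0.00809 and 0.23 without control replicate 1, control replicate 4 or LKB1-deficient replicate 4. Of 5 red cell and platelet markers 2 rose and none fell, also when adjusted over the list alone (median 0.93, camera adjusted p = 0.0498, adjusted p = 0.574 with an estimated correlation). They were Car2 and Car1, carbonic anhydrases, whose CPM was 87.4 and 43.7 in LKB1-deficient replicate 2 and 78.2 and 32.9 in replicate 4, and 11.3 and 3.38 in replicate 1 and 12 and 5.19 in replicate 3. The call of Car1 ended without control replicate 1, 2 or 3 or LKB1-deficient replicate 2 or 4 (adjusted p at most 0.0832). That of the list ended without control replicate 1 or 2 or LKB1-deficient replicate 2 or 4 (adjusted p between 0.0925 and 0.115), and without both of the latter (adjusted p = 0.256). It also ended with replicates 1 to 3 (adjusted p = 0.0507), with DESeq2 size factors (adjusted p = 0.0539) and by fry (adjusted p = 0.125). The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had 0 counts in all libraries. For counted reads this allows at most 0.227 to 0.873 CPM per library (3 counts, counting error only). How reads shared between gene copies were treated is not given in the sources used here, so these zeros set no limit on such reads.

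Of 17 immediate early and heat shock genes, which respond to handling and stress, 5 rose and none fell, also when adjusted over the list alone (median 0.42, camera adjusted p = 0.0188, adjusted p = 0.528 with an estimated correlation). Hsp90aa1, a chaperone, went from 883 ± 97.2 to 1890 ± 469 CPM and Hspa1b, which shares reads with the near-identical Hspa1a, from 1.96 ± 0.335 to 7.16 ± 2.51 CPM. This list's call ended without LKB1-deficient replicate 1 or 2 (adjusted p = 0.0566 and 0.0545) or both replicates 2 and 4 (adjusted p = 0.07). It also ended among genes with a mean CPM of at least 10 (adjusted p = 0.117) and in EU libraries alone (adjusted p = 0.0726). In this list 3 rose without LKB1-deficient replicate 2 or 4. In all, 12 of 29 tested lists passed by camera with the preset correlation, 6 up and 6 down, and 14 passed by fry. With an estimated correlation 0 passed, and 1 had an unadjusted p under 0.05. Other splits of the 8 libraries into 4 and 4 gave up to 14 lists by the preset test.

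**Figure D3:**
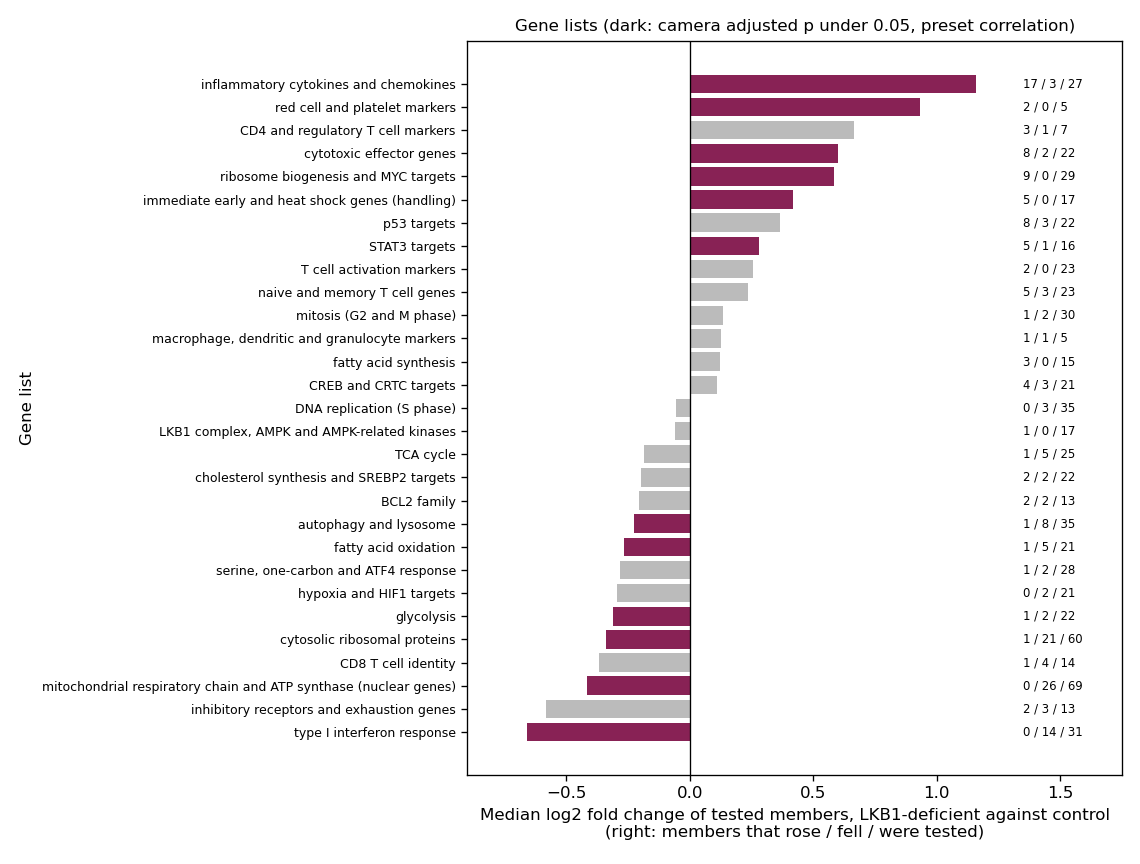
Median log2 fold change (x), LKB1-deficient against control, of the tested members of 29 gene lists (y), with the number of members that rose, fell and were tested at the right. Dark bars mark lists with a camera adjusted p under 0.05 with a preset correlation; the medians run from -0.66 for interferon genes to 1.16 for cytokine genes.

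The groups also differed in library measures. Gene counts were lower in all LKB1-deficient libraries (at most 6356125) than in any control library (at least 7090252), and counts outside annotated genes were 13.2% ± 0.944 in control and 16.2% ± 1.11 in LKB1-deficient libraries (both p = 0.0286 by an exact permutation test on both sides, n = 4 per group, the smallest p that 4 against 4 can give, and 0.0333 adjusted over 7 library measures). Rn45s, a ribosomal RNA precursor, took 0.319% ± 0.0887 and 0.753% ± 0.412 of gene counts (p = 0.0286, adjusted 0.0333, the same exact test). Alignments to several places came to 3.218 ± 0.267 per gene count in control and 2.432 ± 0.234 in LKB1-deficient libraries, without overlap (p = 0.0286, adjusted 0.0333, the same exact test). Fold changes rose with transcript length, from a median log2 of -0.32 in the shortest decile of genes to 0.51 in the longest (Spearman 0.386 across 10350 genes, which are not independent replicates). Each library's own trend on length, as a Spearman coefficient, lay between -0.451 and -0.063 in the controls and between 0.0449 and 0.366 in the LKB1-deficient libraries. With this trend removed, 959 genes were higher and 855 lower. Xist was high and the Y-linked Ddx3y low in replicate 4 of both groups (523 and 922 CPM of Xist, at most 1.69 CPM in the others), so both groups held 1 such library, and the replicates of a group did not all come from the same animal.

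**Figure D4:**
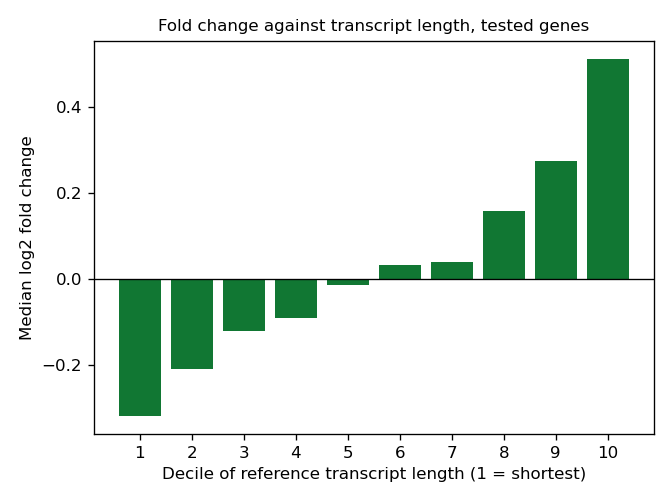
Median log2 fold change (y), LKB1-deficient against control, of tested genes in each decile of reference transcript length (x, shortest first). The bars run from -0.32 in the shortest decile to 0.51 in the longest.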

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

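The counts over other splits of the libraries were planned, and the other tests of explanations in this part were chosen only after the results were seen.

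Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave 2337 genes past the threshold, and the highest other split gave 1 gene. The same held for genes higher (1286, highest other 1) and lower (1051, highest other 1), which are parts of the same result. In each case 1 of 35 splits was as large, the smallest share that 35 splits can give. Every other split mixes the groups, which widens the spread within each side and lowers its counts. The splits also ignore the prefix shared by replicate 1 and the high Xist shared by replicate 4 of both groups. The real grouping thus gave the largest counts, but this test cannot by itself exclude chance. For gene lists, 4 of the 35 splits gave as many as the real 12, and the highest other gave 14, so chance cannot be excluded for the number of lists. Taken list by list, the real split gave the largest median difference of the 35 splits for 12 of 29 lists, those of cytokine, cytotoxic, inhibitory receptor, respiratory chain, cholesterol, autophagy, mitosis, p53, interferon, ribosomal protein, ribosome biogenesis and CD4 T cell genes. The exact p of 0.0286 is the smallest possible and becomes 0.0691 when adjusted over the 29 lists.

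In the cytokine list 17 of 27 genes rose and 3 fell in the LKB1-deficient libraries (camera adjusted p = 0.00016 with the preset correlation, adjusted p = 0.455 with an estimated correlation), which also held fewer counts and a different trend on transcript length. With equal counts in every library the list median was 1.09 (95% interval 0.493 to 2.41, adjusted p = 0.000212 with the preset correlation). With the length trend removed it was 1.42 (adjusted p = 1.07e-06, preset correlation), against 1.16 before. The median did not shrink without the length trend, which argues against that trend as the whole cause. Thinning to equal counts leaves expected ratios nearly unchanged, so it does not test differences in library making that go with depth. The preset test also passed lists in other splits, so its p-values alone do not decide this. CD4 T cells in the LKB1-deficient cultures would bring Cd4, which averaged 0.253 CPM there against a rise of 288 CPM for Gata3, so the tables argue against them too. Whether mast cells or basophils were the source of the whole list is not decided. The summed rise of 12 markers of these cells was 16.3 CPM, 0.504% of the summed rise of the 17 cytokine genes. Without Ifng the share was 1.2%, and the limit chosen for this share lay between these values. The list passed without LKB1-deficient replicates 2 and 4, where Gata2 was highest (median 0.97, 95% interval 0.4 to 2.12, adjusted p = 0.000747). That step may not remove such cells, since 4 of 5 tested markers were still above every control library in LKB1-deficient replicate 1 or 3. This count takes the higher of these libraries at low CPM, so an unchanged marker can enter it. Hdc did, at 2.53 CPM in replicate 1 against at most 2.21 CPM in control (edgeR adjusted p = 0.965 over all libraries). Gata2 was at 2.36 CPM in replicate 3 but at 0.563 CPM in replicate 1, below every control library. A part of such cells in Il9 also stays open (log2 fold change 5.47 without LKB1-deficient replicates 2 and 4, adjusted p = 0.035). So do a direct effect of LKB1 deficiency as a hypothesis and differences in culture or library making that go with the groups, which no test here separates.

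In the respiratory chain and ribosomal protein lists 26 of 69 and 21 of 60 genes fell, and 4 and 1 without control replicate 3 (adjusted p = 0.455 for both lists with an estimated correlation, the other p-values here being with the preset one), and both lists hold short transcripts. Relative to other genes of like length the respiratory chain median was -0.102 (95% interval -0.17 to -0.0616) against -0.418 before. With the trend removed the list still passed (adjusted p = 0.0261), while the number of lower members went from 26 to 6. Most of the size thus went with length. Lengths were those of the longest annotated transcript, which the cells may not use, so the small remainder does not settle whether length is the whole cause. For ribosomal proteins the value relative to genes of like length was -0.0878 (95% interval -0.146 to 0.000228), and with the trend removed the list did not pass (median -0.337 before and -0.0804 after, adjusted p = 0.242) because its fold changes shrank, so the length trend may account for that fall. Without both LKB1-deficient replicates 2 and 4 the medians were -0.309 and -0.334, against -0.418 and -0.337 with all libraries (adjusted p = 1.18e-06 and 7.21e-06 without them). The medians thus stayed lower without these libraries, although 0 members of either list then passed singly in edgeR. The preset test passed up to 14 lists in other splits, so its p-values cannot exclude these libraries as a source. Whether the length trend itself comes from library making or from the cells was not tested.

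In the interferon list 14 of 31 genes fell in the LKB1-deficient libraries (adjusted p = 0.455 with an estimated correlation). The list median was -0.689 with the length trend removed (adjusted p = 5.12e-07 by the preset test). With equal counts it was -0.736 (adjusted p = 4.11e-09 by the same test), and it was -0.657 before either step. The median did not shrink without the length trend, which argues against that trend as the whole cause. Thinning to equal counts leaves expected ratios nearly unchanged, so it does not test differences in library making that go with depth. A direct effect of LKB1 deficiency stays open as a hypothesis, as do differences between cultures or animals, which the labels do not describe.

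In 15 of 274 groups of 4 values, 1 library stood apart from the other 3, where chance alone gives about 1 in 20, or 13.7. In control replicate 1, Irf7 was at 30.1 CPM (others 33.3 to 33.4), Bmyc at 68.1 (59.7 to 60.5), Bcl6 at 7.46 (3.64 to 3.93), Klra7 at 2.25 (1.95 to 1.97) and Il6 at 0.0898 (1.17 to 1.3). In control replicate 2, Nsdhl was at 28 CPM (33.3 to 33.8). In control replicate 4, Csf2rb was at 2.73 CPM (1.06 to 1.3) and Ctsl at 12.5 (10.7 to 11). In LKB1-deficient replicate 3, Pla2g16 was at 86.6 CPM (60 to 63.9), Klrk1 at 64.1 (27.4 to 32.6), Il2ra at 920 (1130 to 1160), Nsdhl at 28.5 (21.3 to 22.1) and Zmat3 at 12.6 (25.3 to 27.4), and 13116 genes were detected there (12499 to 12563). In LKB1-deficient replicate 4, Rn45s took 1.37% of gene counts (0.5301 to 0.5575). Counts outside annotated genes, which the comparisons do not use, averaged 16.18% in the LKB1-deficient libraries, above the control range of 12.13 to 14.27.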

How the results depend on the processing

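Thinning, removal of the length and GC trends, leaving out LKB1-deficient replicates 2 and 4, replicates 1 to 3, EU libraries and the Xist term were chosen after seeing the data, and so was running the gene lists with upper quartile and total count scaling, no filter and the prefix term (10, 11, 11 and 11 lists passed). Of 121 called genes that the naming rule takes, 91 kept their calls whichever library was left out and 30 lost them in at least 1 case; over all alternatives their calls were kept 2577 times, lost 314 times and reversed 0 times. Calls were kept by 114 of 120 after thinning, 105 with the length trend removed, 54 without both LKB1-deficient replicates 2 and 4, and 72 with replicates 1 to 3. Of the 2337 calls, 1475 (63.1%) were shared with the length-corrected fit and 2312 with DESeq2 size factors; the DESeq2 Wald test gave 3047. Leaving out single libraries gave 1011 to 2825 genes, 560 to 1472 higher and 441 to 1353 lower, and 9 to 13 lists. Total count scaling gave 829 higher genes. Fewer libraries left 260 genes (162 higher, 98 lower) without both LKB1-deficient replicates 2 and 4, of which 253 were shared in direction, and 454 (256 and 198) with replicates 1 to 3; EU libraries gave 666 lower. Stricter thresholds gave 437 (248 and 189) at an adjusted p of 0.01 and 177 (116 and 61) against a 1.5-fold change. Camera with an estimated correlation passed 0 lists, and a mean CPM of at least 10, with fewer genes tested, passed 6. The replicate block gave 1902 genes (1075 higher, 827 lower) and 11 lists; same-numbered libraries correlated at -0.251, 0.291, 0.3 and -0.0861, not all over 0.1, so the samples share only a number as far as these values show. Replicate 1 of both groups shares the prefix ET and replicate 4 high Xist, so pairing stays undetermined.

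Reversed values, none of them called, and their causes not tested, were these. Total count scaling: CREB and CRTC targets -0.072253, fatty acid synthesis -0.044403, mitosis -0.034217 and macrophage markers -0.026334. No filter, with more members tested: CD4 and regulatory T cell markers -0.16917 and macrophage markers -0.058886. With the length trend removed: naive and memory genes -0.010682, fatty acid synthesis -0.17203 and Stat3 -0.18965; with GC also removed, fatty acid synthesis -0.15629 and Stat3 -0.17624. EU libraries only: fatty acid synthesis -0.017194, macrophage markers -0.18814, Stk11 0.1026 and Tnf -0.028104. A mean CPM of at least 10: p53 targets -0.01534. Thinned: Stk11 0.027379. Without both LKB1-deficient replicates 2 and 4: Stk11 0.17691 and Il17a 0.11597; with replicates 1 to 3, Stk11 0.029521. Upper quartile and total count scaling: Stat3 -0.021081 and -0.074295. Leaving out single libraries, fatty acid synthesis ran from -0.0028172 to 0.21835, macrophage markers from -0.12453 to 0.22584, Stk11 from -0.22425 to 0.079113 and Stat3 from -0.11809 to 0.19706. With depth down to 3454388 counts and 4 libraries per group, simulated 1.5-fold changes were mostly missed (4.48% recovered), so an uncalled gene is not shown to be unchanged.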

Other observations

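The test in this part was chosen only after the results were seen, and so were its gene list and the mast cell list. Of 12 genes of mast cells and basophils 5 were tested, 2 rose and 0 fell. Gata2, a transcription factor of these and other blood cells, was 1.23 ± 0.365 CPM in control and 5.22 ± 4.44 CPM in LKB1-deficient libraries (adjusted p = 0.0422), with 9.62 and 8.36 CPM in LKB1-deficient replicates 2 and 4, where Car1 and Car2 were also highest. Il1rl1, the receptor of IL-33, was 3.44 ± 1.43 and 9.09 ± 3.78 CPM (adjusted p = 0.0296). Mcpt8 was 1.32 ± 0.49 and 3.26 ± 1.72 CPM (adjusted p = 0.0511), Kit 1.37 ± 0.323 and 2.04 ± 1.1 CPM (adjusted p = 0.369) and Hdc 1.71 ± 0.389 and 1.84 ± 0.833 CPM (adjusted p = 0.965). Of those not tested, Cpa3 was 0.707 ± 0.386 and 2.39 ± 1.84 CPM, Ms4a2 0.411 ± 0.113 and 1.42 ± 0.681 CPM, Cma1 0.177 ± 0.0865 and 1 ± 0.907 CPM and Fcer1a 0.144 ± 0.121 and 0.135 ± 0.27 CPM, Tpsb2 and Prss34 averaged at most 0.37 CPM in either group, and Mrgprb1 had 0 counts.

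The rise of Gata3, Il13 and Il9 prompted the hypothesis that a wider set of type 2 T cell genes is higher. Of 15 such genes not named in the report, 10 were tested, 4 rose (Ccr8, Tnfrsf8, Cysltr1 and Stat5a) and 0 fell (5 rose when adjusted over the list alone; median log2 fold change 0.51). Ccr8, Tnfrsf8 and Cysltr1 were low, at 2.67, 0.261 and 1.08 CPM in control and 7.72, 2.47 and 6.48 CPM in LKB1-deficient libraries. Of the better expressed members Stat5a went from 187 to 269 CPM. Il4ra, Nfil3, Stat6 and Stat5b did not pass in edgeR (adjusted p = 0.113, 0.379, 0.9 and 0.884). The camera p was 0.00199 with the preset correlation and 0.156 with an estimated correlation, so the hypothesis met the first test and not the second, and it may hold for part of the list only.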
